A study of Homo sapiens with 16 samples.

How the data were processed

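Strand-specific libraries of polyadenylated RNA from HEK293T cells were prepared with the NEBNext Ultra II Directional kit after oligo(dT) selection, per the labels' protocols. Guides were integrated as pairs at the AAVS1 locus of cells with doxycycline-inducible Cas9, which was induced for 4 days (AQR, SF3B5, SF3B6 and FLUC, 1 library each) or 7 days (GCN1 guides 1 and 2, GCN1 guides 3 and 4, and FLUC, at 0 h and after 6 h of harringtonine, 2 libraries each), per the labels. The labels give harringtonine at 1 mM, a unit that could not be checked here. Reads were aligned to GRCh38 with STAR 2.7.11a, per the submitters' processing notes. The annotation version is not given in the sources used here.

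The deposited values are whole counts of reads per gene from STAR, 1 file per library with 62096 gene identifiers, and hold unstranded counts and counts on each strand. The counts on the reverse strand were used, since that strand held most gene reads in every library, as the kit predicts. STAR's summary counts of unmapped, multimapping and outside-exon reads in the deposited files were used for the shares of reads. Gene symbols, types and coordinates came from GENCODE v44 (GRCh38), in which 62072 of the identifiers were found. The other identifiers carry no symbol and are not named. Coordinates are 1-based.

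Groups were taken from the sample labels. For the 6 libraries of the 6 h groups the genotype in the label differs from that in the file name, and the genotype by file names was an alternative for each comparison between genotypes at 6 h. These choices, the gene lists, the tests and the rule for naming genes were fixed before the data were examined. The labels give the replicate number as a batch, so a fit with this number as a block was made beside the fit without it, which gives the 7-day values unless another fit is named. Correlations between the deviations of same-numbered libraries from their group means had a median of −0.000857 over 15 pairs of groups (lowest −0.142, highest 0.0741).

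The 12 libraries of the 7-day experiment were fitted together with edgeR 4.0.16 (R 4.3.3) as 6 groups without the block, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over the 16182 genes tested, called at 0.05. The coefficient of variation between replicates was 10.6%. Nothing in the labels says that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. Contrasts were knockout against FLUC at 0 h (all 4 knockout libraries and each guide pair), 6 h against 0 h averaged over genotypes, labelled knockout against labelled FLUC at 6 h, and the difference between labelled genotypes in the response. Alternatives were DESeq2 1.42.0, RLE factors, library totals without TMM, no filter, unstranded counts, the replicate block, a fit of only the groups compared, each library left out in turn, and genotype by file names. For the drug contrast, leaving out the 6 h pair labelled guides 3 and 4 and crossing the replicate numbers of guides 1 and 2 at 0 h were added after seeing the data.

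Gene lists, 20 in all, were tested with camera in limma 3.58.1 at a correlation of 0.01 and with an estimated correlation, adjusted over the 20. They are immediate early genes, ATF4 and integrated stress response targets, NF-kB genes, interferon-stimulated genes, p53 targets, cytosolic ribosomal proteins, replication-dependent histones, heat shock genes, unfolded protein response genes, U2 snRNP and SF3b genes, intron-binding and PRP19 complexes, SR proteins and CLK kinases, NMD factors, snoRNA host genes, cholesterol synthesis genes, mitotic genes, GCN and ribosome collision factors, mitochondrially encoded mRNAs, markers of other cell types, and single-exon protein-coding genes (985 in the annotation). The first 19 hold 427 genes, all of which were matched. In the 4-day experiment 18 lists had enough measured members, and the interferon-stimulated genes and markers of other cell types did not.

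The 4-day libraries were compared as log2 ratios of CPM with TMM scaling and a prior count of 1, over genes with at least 100 counts in 1 of the 2 libraries. No test was made. Intervals are exact 95% intervals for the ratio of 2 counts and cover counting error only. A list's median was placed among 10000 random lists of the same size matched over 20 expression bins. Ratios with minimums of 20 and 500 counts, library totals, unstranded counts, all libraries thinned to 7688236 counts and a prior count of 5 were the alternatives. Unchanged libraries against the shared control were simulated 100 times for 4 days and 40 times for the guide pairs at 0 h.

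Named genes were the targets, then for the 7-day contrasts the 8 largest rises and falls among called genes with a mean of at least 5 CPM, an annotated symbol, no pseudogene and no overlap between the libraries compared, and up to 4 members of each list with the smallest p. For 4 days they were the 5 largest rises and falls among measured genes with a symbol, and up to 4 list members with the largest ratios. Genes named to spell out a count of 5 or fewer in a list, the genes called with each guide pair, SUPT6H and the genes of the interaction were chosen after their values were seen. Single values of 2 genes are not reported here.

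Silent genes were protein-coding genes outside the mitochondrial and Y chromosomes with 0 reads on either strand in all 12 libraries of the 7-day experiment, or in the other 11 for a library of that experiment. For the 4-day libraries they number 1672, with 3.19 Mb of exon. Nested genes were 3099 genes with no sense read in the 7-day libraries that lie inside an expressed protein-coding host (at least 1 CPM) on the other strand and touch no exon of that strand, 1.80 Mb in all. Their reads on the other strand were subtracted from those on the host strand, and the result was scaled to gene counts.

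Single values were compared by exact permutation tests in scipy 1.17.1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3), and figures were drawn with matplotlib 3.10.9. The counts in annotated genes at 4 days were 8770697 for AQR, 12588292 for SF3B5, 14014412 for SF3B6 and 14719187 for FLUC. At 7 days and 0 h they were 11035800 and 7688236 (replicates 1 and 2) for guides 1 and 2, 12009700 and 11439017 for guides 3 and 4 and 12261395 and 11480534 for FLUC, and in the 6 h pairs labelled in the same order 10909693 and 11393035, 12661115 and 11727127, and 13116217 and 11432563. Replicates differed by 3.78 to 17.1 times counting noise (chi-square per degree of freedom), so none is a copy of another. On simulated counts with known changes, the 0 h test recovered 66, 80, 92 and 100% of genes changed 1.5, 2, 4 and 8-fold (50 each) with 17 false calls of 15717. The drug test recovered 84, 90, 100 and 100% with 12 false calls of 15719, and the 6 h test 50, 82, 98 and 100% with 9 of 15715. The 4-day ratios recovered 100% of 200 genes changed 4-fold, with 17 unchanged genes over 2-fold among 10313 tested. The simulations gave each gene 1 spread for all libraries and held no outlying library. They do not show how the tests act where replicates are as unlike as some of these. False calls are set beside all genes tested, not beside all calls.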

Results

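Polyadenylated RNA was sequenced from HEK293T cells, a line derived from human embryonic kidney, after CRISPR knockout of genes of RNA metabolism. In the first experiment Cas9 was induced for 4 days with guides against AQR, SF3B5 or SF3B6 or with the non-targeting control FLUC, with 1 library each. In the second it was induced for 7 days with GCN1 guides 1 and 2, GCN1 guides 3 and 4, or FLUC, and cells were taken without drug (0 h) or after 6 h of harringtonine, with 2 libraries in each of the 6 groups. The 16 libraries held between 7688236 and 14719187 counts in annotated genes. For the 6 libraries of the 6 h groups, the sample labels and the names of the deposited files give different genotypes: the pair labelled GCN1 guides 1 and 2 has files named for guides 3 and 4, the pair labelled guides 3 and 4 has files named for FLUC, and the pair labelled FLUC has files named for guides 1 and 2. Genotypes at 6 h are those of the labels and are called labelled throughout. Directions between them rest on labels that the file names contradict. The comparison of 6 h with 0 h pools all genotypes and does not depend on this.

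GCN1 (chromosome 12, 120127202 to 120194715, GRCh38) encodes a ribosome-bound scaffold that activates the kinase GCN2 and acts when ribosomes collide. At 0 h its level was 212 ± 41.8 CPM (TMM-scaled; SD, n = 2) with guides 1 and 2, 162 ± 7.02 with guides 3 and 4 and 451 ± 26.8 in FLUC, which is 2.43-fold lower in the knockouts. All 4 knockout libraries lay below both FLUC libraries (two-sided exact permutation test over 15 arrangements, p = 0.0667, the smallest this design allows). At 6 h GCN1 was at 185 ± 17.9 CPM in the pair labelled guides 1 and 2, 121 ± 13.1 in the pair labelled guides 3 and 4 and 213 ± 18.7 in the pair labelled FLUC (n = 2 each). The log2 difference between labelled knockout and labelled FLUC was −0.50 (exact permutation p = 0.133), and the lowest labelled FLUC library, at 199 CPM, was 1.48 CPM above the highest labelled knockout library, while replicates of 1 pair differed by up to 26.5 CPM. Grouped by file names the difference had the other sign, 0.71 (exact permutation p = 0.0667). No 6 h library reached the 432 CPM of the lower FLUC library at 0 h, the highest being 226 CPM. The target level did not separate the 6 h labels beyond the range of replicates.

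**Figure D1:**
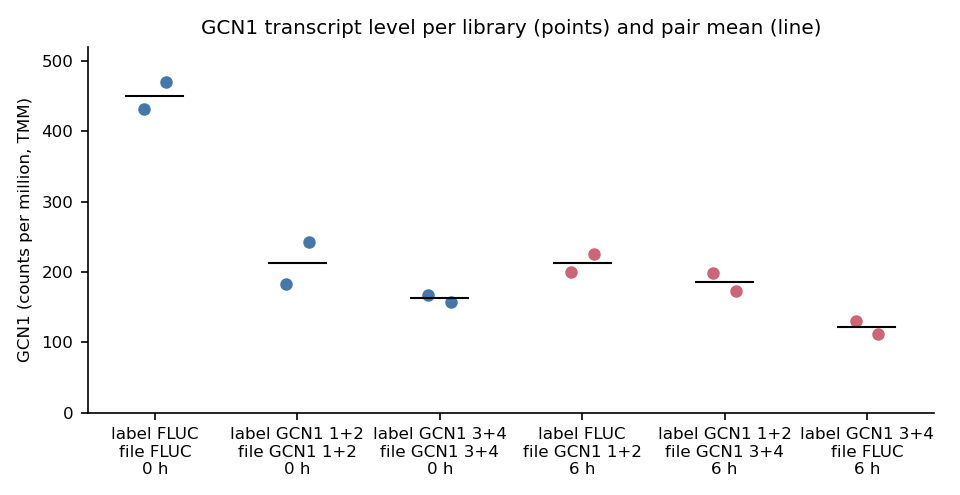
GCN1 transcript level in CPM for each of the 12 libraries of the 7-day experiment, grouped by label with the genotype of the file name beneath, with a line at each pair's mean. At 0 h the FLUC pair lies at 451 CPM against 212 and 162 CPM in the knockout pairs, and at 6 h all libraries lie at or below 226 CPM.

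Before drug, the transcription factor EGR1 was called higher in the GCN1 knockouts. DDIT4, SLC7A11 and PSAT1, which are targets of ATF4, the transcription factor downstream of GCN2, were called lower. This comparison asks what loss of GCN1 does to unstressed cells. These calls were all lost in a fit of only the groups compared, and none was made with guides 3 and 4 alone. EGR1 (chromosome 5, 138465479 to 138469303) was at 10.4 ± 1.95 CPM with guides 1 and 2 and 8.15 ± 1.64 with guides 3 and 4 against 3.88 ± 0.494 in FLUC (n = 2 each), a log2 fold change of 1.23 (SE 0.21, adjusted p = 0.00913). In all, 14 of 16182 genes rose and 8 fell, 6 and 1 of them over 2-fold. GCN1 itself fell by 1.28 on the log2 scale (SE 0.11, adjusted p = 4.7e-07). The kinase gene MAPK15 rose most, by 2.84-fold (log2 SE 0.29, adjusted p = 0.025). GPR50, an orphan relative of the melatonin receptors, rose by 1.15 (SE 0.16, adjusted p = 0.00151). TMEM145 rose by 1.07, TMEM63C by 0.96, the transcriptional repressor gene KCTD1 by 0.85, the vesicle protein gene SCAMP5 by 0.83 and the growth factor gene BMP2 by 0.75. Among falls, the collagen receptor DDR2 dropped by 0.96 (SE 0.14, adjusted p = 0.003), the cystine transporter SLC7A11 by 0.81 (SE 0.15, adjusted p = 0.0243), the mTORC1 inhibitor DDIT4 by 0.76 (SE 0.12, adjusted p = 0.00479) and the G1 cyclin CCND1 by 0.74 (SE 0.12, adjusted p = 0.00913). SERPINF1 fell by 0.71, the haem oxygenase HMOX1 by 0.55 and the serine synthesis enzyme PSAT1 by 0.53. With the replicate number as a block 17 of the 22 remained called, and TMEM63C (adjusted p = 0.0558), BMP2 (0.0758), FOSB (0.0529), HMOX1 (0.0563) and SUPT6H (0.0541, named here after its values were seen) did not. The count rested on single libraries: it was 1307 without replicate 1 of guides 1 and 2, 68 without replicate 2 of these guides, 5 without either library of guides 3 and 4, and 1 or 4 without replicate 1 or 2 of FLUC. GCN1 was the only gene called in all 6 of these fits.

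Replicate 2 of guides 1 and 2 at 0 h was unlike replicate 1. Its unmapped reads were 49.1% against 35.3%, and its reads outside exons 8.78% against 5.51%. Between these libraries 83 genes differed over 2-fold, against at most 32 between replicates of any other group. Without replicate 1 this library stands alone for its group. Counts from such fits, above and below, rest on it and cannot be read as more genes changed by GCN1 loss. Each guide pair was also set against FLUC alone at 0 h. With guides 1 and 2, 5 genes rose (GPR50, MAPK15, EGR1, TMEM145 and SUPT5H) and 4 fell (GCN1, DDR2, SERPINF1 and DDIT4). With guides 3 and 4, GPR50 rose and GCN1, DDR2 and CCND1 fell, and with the replicate number as a block CCND1 was not called (adjusted p = 0.0704). GCN1 fell by 1.09 (SE 0.13) with guides 1 and 2 and by 1.47 (SE 0.13) with guides 3 and 4. GPR50 rose in both (log2 fold changes 1.23 and 1.07), and GCN1 and DDR2 fell in both, where unchanged groups sharing these controls gave 0 shared rises and 0.025 shared falls on average over 40 simulations, and independent lists would share 0.000309 and 0.000742. Across genes, which are not independent replicates, the fold changes of both pairs correlated at r = 0.579 against 0.483 simulated, with a covariance of 0.121 against 0.0683, and part of the excess may come from the shared FLUC libraries. Between the guide pairs, 0 genes were called by edgeR, with 524 at an unadjusted p under 0.05 and 0 called by DESeq2. The count for guides 1 and 2 was 2523 and 14 without replicate 1 and 2 of these guides and 1 and 2 without replicate 1 and 2 of FLUC. For guides 3 and 4 it was 1 whichever of its 4 libraries was left out.

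Immediate early genes, which encode the transcription factors and phosphatases induced first after a stimulus, rose as a group at 0 h (camera adjusted p = 1.8e-10, and adjusted p = 0.0258 with an estimated correlation). Of 37 measured, EGR1, ATF3 (0.57), ARC (1.34) and FOSB (1.47) rose and 0 fell, and 9 rose when adjusted over the list alone. ATF4 targets fell (camera adjusted p = 2.6e-10, and 0.0162 estimated): of 29, DDIT4, SLC7A11 and PSAT1 fell and 0 rose, and adjusted over the list alone 10 fell and 1 rose. Replication-dependent histone genes fell (camera adjusted p = 8e-10, and 0.0258 estimated) with 0 of 21 called singly by edgeR, 11 at an unadjusted p under 0.05, 1 by DESeq2 and 5 falls adjusted over the list alone. H3C1 had a log2 fold change of −1.09 (adjusted p = 0.193). Most histone transcripts lack a poly(A) tail, so these values cover the fraction that oligo(dT) captured. Cholesterol synthesis genes also fell (camera adjusted p = 2.6e-06, and 0.0258 estimated) with 0 of 19 called by edgeR, 10 at an unadjusted p under 0.05, 0 by DESeq2 and 5 falls adjusted over the list alone. HMGCS1 stood at −0.47 (adjusted p = 0.236) and IDI1 at −0.48 (adjusted p = 0.267).

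A further 5 lists passed camera at its preset correlation of 0.01 and were lost with an estimated one. Cytosolic ribosomal protein genes fell (camera adjusted p = 5.4e-11; adjusted p = 0.571 with an estimated correlation) with 0 of 78 called by edgeR, 20 at an unadjusted p under 0.05, 1 by DESeq2 and 2 falls adjusted over the list alone. RPS27 was at −0.46. Mitochondrially encoded mRNAs fell (0.00193 and 0.571) with 0 of 13 called by edgeR, 4 unadjusted, 0 by DESeq2 and 0 adjusted over the list alone. NF-kB genes rose (0.00606 and 0.0723) with 0 of 11 called, 1 unadjusted, 0 by DESeq2 and 0 adjusted over the list alone, and LIF was at 1.82 (adjusted p = 0.349). The p53 targets rose (0.0214 and 0.183) with 0 of 19 called, 6 unadjusted, 1 by DESeq2 and 2 rises adjusted over the list alone, with AEN at 0.45. SR proteins and CLK kinases fell (0.0214 and 0.603) with 0 of 18 called, 6 unadjusted, 2 by DESeq2, and 1 rise and 2 falls adjusted over the list alone, with SRSF9 at −0.37. The other 11 lists were not called. All 3 markers of other cell types were at an unadjusted p under 0.05, with 0 called by edgeR or DESeq2, and 2 rose and 1 fell adjusted over the list alone. Their camera adjusted p was 0.149 for GCN and ribosome collision factors, where GCN1 was the only member called, 0.34 for mitotic genes, 0.461 for NMD factors and for markers of other cell types, 0.736 for heat shock and interferon-stimulated genes, 0.821 for U2 and SF3b genes, 0.891 for unfolded protein response, snoRNA host and single-exon genes, and 0.948 for the intron-binding and PRP19 complexes. The median was positive and the test negative for the collision factors, heat shock genes, PRP19 complexes and snoRNA hosts.

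Harringtonine, which stops ribosomes just after initiation, was compared with no drug over 6 and 6 libraries to ask how the transcriptome follows a block of translation. EGR1 showed the largest rise among the genes named here, with a log2 fold change of 5.70 (SE 0.11, adjusted p = 6.4e-22), although it averaged only 12.1 CPM in the 6 h pair labelled guides 3 and 4. The AP-1 and early response genes IER2 (4.01, SE 0.09), ATF3 (3.93, SE 0.07) and JUN (3.88, SE 0.08) and the MAP kinase phosphatase DUSP1 (3.95, SE 0.07) rose in every 6 h library above every 0 h library. The next largest such rises were DUSP8 (3.17), TIPARP (3.11), HES1 (3.06) and the histone gene H2AC6 (3.06). The largest falls were in MIR600HG (−2.60, SE 0.14), the laminin gene LAMA1 (−2.47, SE 0.16), the endocytic receptor LRP1 (−2.43, SE 0.13) and the actin crosslinker FLNA (−2.35, SE 0.08), followed by LRRC3 (−2.29), RIMS3 (−2.12), the TRAIL decoy receptor TNFRSF10D (−2.10) and PPP1R26 (−2.02). GCN1 fell by 0.57 (SE 0.08, adjusted p = 1e-06). In all, 4587 of 16182 genes rose and 4581 fell, 1086 and 640 of them over 2-fold. With library totals in place of TMM, 5291 rose and 3741 fell, so the even balance depends on the scaling.

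Among lists, immediate early genes rose with the drug: 28 of 37 rose and 2 fell (NR4A1 and SRF), with the same numbers adjusted over the list alone (camera adjusted p = 1.6e-44, and 0.00383 with an estimated correlation). Histone genes rose, 19 of 21 up and H3C1 down (3.6e-17 and 0.0128), H1-2 by 1.40. Of 19 p53 targets 12 rose, among them GADD45A (1.74) and AEN (1.40), while BAX and CCNG1 fell (0.000361 and 0.0411). Of 29 ATF4 targets 21 fell, SLC7A11 by 1.91 and SLC7A5 by 1.17, whereas ATF4, CTH, DDIT3, GDF15 and SLC3A2 (1.10) rose (0.000107 and 0.0411). Heat shock genes fell, 10 of 13 down, with HSPA1B at −1.84 and HSPA8 at −0.89, and BAG3 up (1e-05 and 0.0411). These 5 lists kept their call with an estimated correlation, and in each the numbers adjusted over the list alone were the same. The drug values average 6 h pairs that were unlike. By file names, the GCN1 minus FLUC difference in response had a median of 1.30 for histones, with 16 of 21 called above 0 and 0 below. Its median was 1.37 for immediate early genes (19 of 37 above, 1 below) and 0.59 for ribosomal protein genes (56 of 78 above, 0 below).

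The other 7 called lists were lost with an estimated correlation. All 13 mitochondrially encoded mRNAs fell, MT-ATP6 by 1.25 and MT-CO3 by 1.02 (camera adjusted p = 3.2e-11; adjusted p = 0.113 with an estimated correlation). Of 78 ribosomal protein genes 75 fell and 0 rose, RPS23 by 0.67 and RPL7 by 0.54 (1.4e-13 and 0.302). Of 17 unfolded protein response genes 12 fell and 0 rose, PDIA4 by 0.95 and HSPA5 by 0.84 (0.000107 and 0.051). Of 19 cholesterol synthesis genes 11 fell, INSIG1 by 1.23, and HSD17B7 and MVK rose (0.000493 and 0.0532). Of 16 snoRNA hosts 11 rose, SNHG15 by 1.92 and SNHG17 by 1.63, and DANCR, SNHG3, SNHG5 and SNHG16 fell (0.000326 and 0.124). Of 18 SR proteins and CLK kinases 11 rose, CLK4 by 1.31 and CLK1 by 1.14, and SRSF1 and SRSF9 fell (0.00257 and 0.318). Of 10 NMD factors 7 rose and 0 fell, SMG9 by 1.35 and UPF3A by 0.62, and adjusted over the list alone 7 rose and 1 fell (0.0219 and 0.185). For the other 6 of these the numbers adjusted over the list alone were the same.

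Lists not called for the drug also held called genes, as would most lists, since 9168 of all 16182 genes were called. Of 20 GCN and collision factors 9 rose, RNF25 by 1.18, and 5 fell, GCN1, EIF2AK4, EIF4E2, EDF1 and PELO (camera adjusted p = 0.201). Of 15 members of the intron-binding and PRP19 complexes 9 rose, AQR by 0.59, and CWC15 fell by 1.00 (0.102). KIF11 rose and 9 of 19 mitotic genes fell (0.128). Among U2 and SF3b genes DDX42, PHF5A, SF3A1, SF3A2 and SF3B3 rose and SF3B6 and SNRPB2 fell (0.56). ISG15 and STAT2 rose and IFI6, IFIT1, IFITM1 and IRF9 fell among 10 interferon-stimulated genes (0.793). COL1A1 (−0.97) and COL3A1 fell among 3 markers of other cell types (0.164). Of 11 NF-kB genes LIF and NFKBIA rose and NFKBIZ fell, and adjusted over the list alone only the rises remained called (0.708). Of 237 single-exon genes 72 rose and 87 fell (0.346). With library totals the falls called went from 9 to 5 for mitotic genes, from 4 to 1 for interferon-stimulated genes and from 87 to 75 for single-exon genes, of which 76 rose. With the replicate number as a block NFKBIZ was not called (adjusted p = 0.0513).

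At 6 h, immediate early genes were far lower in the pair labelled GCN1 guides 3 and 4, whose files are named for FLUC, than in both other pairs. EGR1 was at 12.1 ± 2.90 CPM there, against 1921 ± 118 in the pair labelled guides 1 and 2 and 1972 ± 324 in the pair labelled FLUC (n = 2 each). ATF3 stood at 67.8 ± 2.86, 1747 ± 118 and 1548 ± 82.3 CPM in the same order. The comparison of labelled knockout with labelled FLUC asks whether GCN1 shapes the response to a translation block. It gave lower EGR1 (log2 fold change −3.69, SE 0.12, adjusted p = 2.9e-16), FOS (−2.76, SE 0.13, adjusted p = 4.4e-13), ATF3 (−2.17, SE 0.09, adjusted p = 3.2e-14) and DUSP1 (−1.66, SE 0.09, adjusted p = 4e-12) on the average of the pairs labelled knockout. In the pair labelled guides 1 and 2, both libraries lay above both labelled FLUC libraries for FOS, ATF3 and DUSP1. The SEs come from the spread within pairs, not between the pairs labelled knockout. Among genes with no overlap between labelled groups, the largest falls were FOSB (−1.92, SE 0.18), the microRNA host MIR222HG (−1.81, SE 0.18) and the eIF2-alpha phosphatase subunit PPP1R15A (−1.08, SE 0.11), followed by HELZ2, P2RY11, MAFG, BRSK1 and the talin gene TLN1 (−0.88, SE 0.11). The largest rises were the receptor kinase KIT (1.49, SE 0.22), the BH3-only gene BMF (1.39, SE 0.23), the guanylate cyclase subunit GUCY1A1 (1.37, SE 0.25) and the ephrin receptor EPHA3 (1.19, SE 0.26), followed by NHS, TLCD4, PDE5A and CNTN1. Without replicate 2 of labelled FLUC, EPHA3 (adjusted p = 0.215), NHS (0.191), PDE5A (0.208), CNTN1 and P2RY11 (0.0649) lost their call, and CNTN1 (0.2 at the highest) also without replicate 2 of labelled guides 1 and 2. GCN1 fell by 0.50 (SE 0.11, adjusted p = 0.00856). In all, 679 genes rose and 962 fell, 52 and 61 of them over 2-fold. Grouped by file names, 2084 genes rose and 1867 fell, and all 1641 genes called under the labels had the opposite sign, EGR1 being at 7.33. With library totals in place of TMM, 1428 rose and 451 fell under the labels and 918 and 3674 by file names, so the balance of rises and falls depends on the scaling.

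The labelled knockout groups were not alike. Between the pairs labelled guides 1 and 2 and FLUC, edgeR called 0 genes, with 1506 at an unadjusted p under 0.05 and 0 called by DESeq2. Between the pairs labelled guides 3 and 4 and FLUC, 1837 genes rose and 2157 fell, EGR1 having a log2 fold change of −7.35. Between the pairs labelled guides 1 and 2 and guides 3 and 4, 1002 were higher and 773 lower, with EGR1 at 7.31. The 0 h groups of both guide pairs gave 0 calls against each other. Single libraries moved the count of 1641 for labelled knockout against labelled FLUC: it was 95 and 619 without replicate 2 and 1 of labelled FLUC, 377 without replicate 2 of labelled guides 1 and 2, and 318 without replicate 2 of labelled guides 3 and 4. In these fits GCN1 lost its call without replicate 2 of any of the 3 pairs (adjusted p = 0.24, 0.0527 and 0.0628 in the order just given), and the lone library left is assumed to vary like the other groups.

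**Figure D2:**
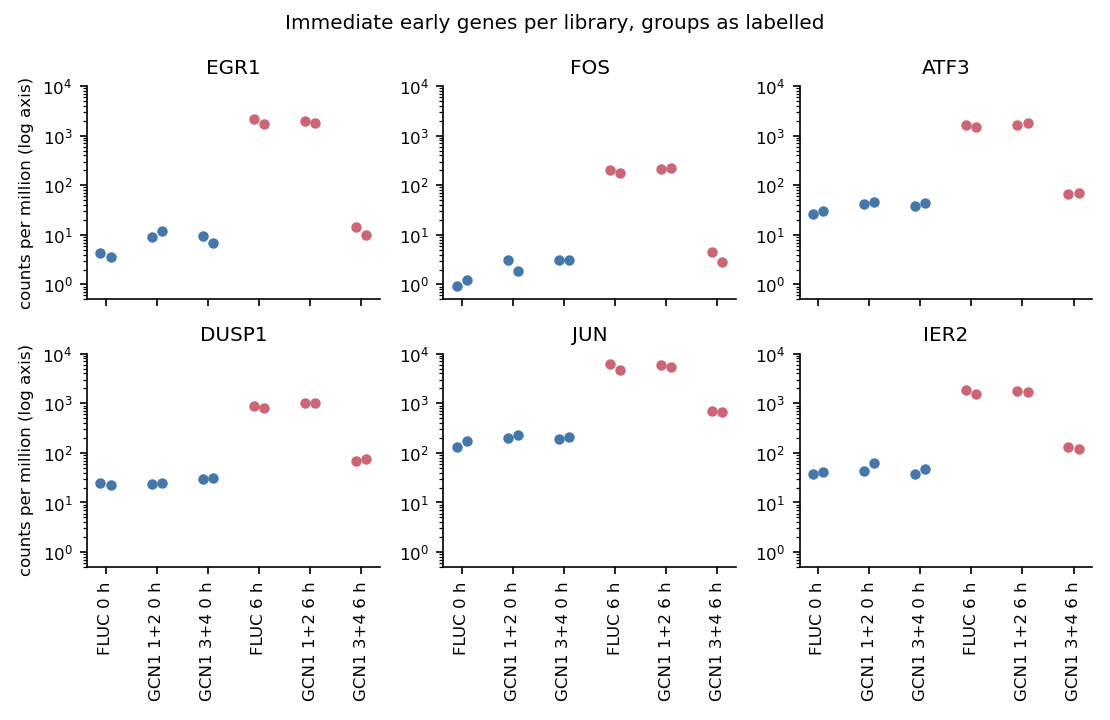
Level of 6 immediate early genes in CPM (log axis) in each of the 12 libraries of the 7-day experiment, grouped by label. In the 6 h pair labelled GCN1 guides 3 and 4 EGR1 averages 12.1 CPM, against 1921 and 1972 CPM in the other 6 h pairs.

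Of 37 immediate early genes 22 fell and KLF10 rose in the labelled comparison, and adjusted over the list alone 24 fell and 2 rose (camera adjusted p = 1.1e-56, and 0.00152 with an estimated correlation). The other 6 called lists were lost with an estimated correlation. Ribosomal protein genes fell, 24 of 78 and 39 adjusted over the list alone, RPL26 by 0.78 (camera adjusted p = 1.3e-12; adjusted p = 0.456 with an estimated correlation). Histone genes fell, 6 of 21 and 7 adjusted over the list alone, H1-2 by 0.71 and H3C2 by 0.64 (0.000227 and 0.143). U2 and SF3b genes fell, with SF3A1, SF3B2 (−0.47) and SF3B4 called of 15 and 6 adjusted over the list alone (0.00557 and 0.143). MT-CO1 (0.39) was the only mitochondrial mRNA of 13 called, also when adjusted over the list alone, and the list rose (0.0198 and 0.53). NMD factors fell, with SMG5 (−0.56), SMG6 and UPF1 called of 10 and 4 adjusted over the list alone, as did the PRP19 complexes, with BUD31, PRPF19 and XAB2 called of 15 and 5 adjusted over the list alone (both 0.0485 and 0.456), and both lists were lost with a replicate block (adjusted p = 0.0501). With library totals the falls called went from 24 to 5 for ribosomal protein genes, from 6 to 4 for histones, from 3 to 1 for U2 and SF3b genes and for NMD factors and from 3 to 0 for the PRP19 complexes. The rises called among mitochondrial mRNAs went from 1 to 4, so these numbers depend on the scaling. MT-CO1 lost its call without replicate 2 of labelled FLUC (adjusted p = 0.362), of labelled guides 1 and 2 (0.113) and of labelled guides 3 and 4 (0.0698). Without replicate 2 of labelled FLUC, RPL26 (0.0808), H3C2 (0.0872), SMG5 (0.18) and SF3B2 (0.204) lost theirs too, as did H3C2 without replicate 1 of labelled FLUC (0.0502) and SF3B2 without replicate 2 of labelled guides 3 and 4 (0.0581).

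ATF4 targets went both ways at 6 h and the list was not called (camera adjusted p = 0.752). DDIT3 fell by 0.82 (SE 0.16), SESN2 by 0.57 (SE 0.11) and SLC7A5 too, while XPOT rose by 0.55 (SE 0.12) with 3 other targets, among them DDIT4 and PSAT1. CDKN1A fell by 0.84 (SE 0.15) with 4 other p53 targets, AEN, BAX, PLK3 and TNFRSF10B, and SESN1 rose. Without replicate 2 of labelled FLUC, DDIT3 (adjusted p = 0.119), SESN2 (0.134), XPOT (0.18) and CDKN1A (0.123) were not called, nor was XPOT without replicate 1 (0.051). In the other lists not called, AURKB, MKI67 and PLK1 fell of the mitotic genes, SNHG15, SNHG16 and ZFAS1 of the snoRNA hosts, DNAJB1 and HSPA1B of the heat shock genes, and EDF1 and GCN1 of the collision factors, where IMPACT rose. HYOU1 fell of the unfolded protein response, SREBF2 of cholesterol synthesis, CLK3 of the SR and CLK genes, IFI27 of the interferon-stimulated genes and COL1A1 of the other-cell markers, whose median was positive and test negative. Of single-exon genes 10 rose and 15 fell. With library totals 24 of them rose and 11 fell, 4 collision factors rose and 1 fell, and 2 rose and 0 fell among cholesterol synthesis, SR and CLK, and interferon-stimulated genes each, so the direction in these lists depends on the scaling. Of 11 NF-kB genes edgeR called 0, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2. With the replicate number as a block EDF1 (adjusted p = 0.0518), IFI27 (0.0561), CLK3 (0.0624) and PLK1 (0.0632) were not called, nor was SF3A1 of the U2 and SF3b genes (0.0579).

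The difference between labelled knockout and labelled FLUC in the response to harringtonine was tested as an interaction. EGR1 responded less under the labels (−4.93 on the log2 scale, adjusted p = 1.6e-12), as did FOS (−4.15, adjusted p = 1.4e-08) and ATF3 (−2.74, adjusted p = 6.5e-12), and KIT responded the other way (1.86, adjusted p = 0.000406). These 4 genes were chosen after their values were seen. EGR1 rose by 1.63 with the drug in the FLUC libraries of the file names and by 7.73 in the GCN1 libraries of the file names, an interaction of 6.10. Under the labels the interaction was above 0 for 754 called genes and below 0 for 849, and under the file names for 526 and 275. A value above 0 is a stronger rise or a weaker fall with the drug in the knockout, and is counted as a rise. These counts therefore do not say in which genotype the response was stronger. With library totals the labels gave 1011 and 660 and the file names 204 and 1030, so this balance depends on the scaling too. The total of 1603 was 4778 without replicate 1 of guides 1 and 2 at 0 h, 817 and 718 without replicate 1 and 2 of guides 3 and 4 at 0 h, and 102 without replicate 1 of FLUC at 0 h. Of the 6 h libraries, leaving out replicate 2 gave 599 for labelled guides 1 and 2, 589 for labelled guides 3 and 4 and 161 for labelled FLUC, and leaving out replicate 1 gave 955 for labelled FLUC.

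Reads outside annotated exons, from introns and between genes, made up 6.76% ± 1.26 of uniquely mapped reads at 0 h and 5.27% ± 0.505 at 6 h (SD, n = 6 each; two-sided exact permutation test over 924 arrangements, p = 0.0108). With libraries paired by group and replicate number, 5 of 6 pairs were lower at 6 h (exact sign-flip p = 0.0938), and with the 6 h groups taken from the file names 6 of 6 were (exact sign-flip p = 0.0313). In the 4-day libraries the share was 20.8% in the AQR knockout, 17.3% in SF3B5, 14.0% in SF3B6 and 9.52% in FLUC, and all 4 lay above every 7-day library, of which the highest was at 8.78%. Genes with no read in any 7-day library held reads on both strands nearly alike in the 4-day libraries, 1157 sense and 1044 antisense in AQR and 116 and 114 in FLUC.

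**Figure D3:**
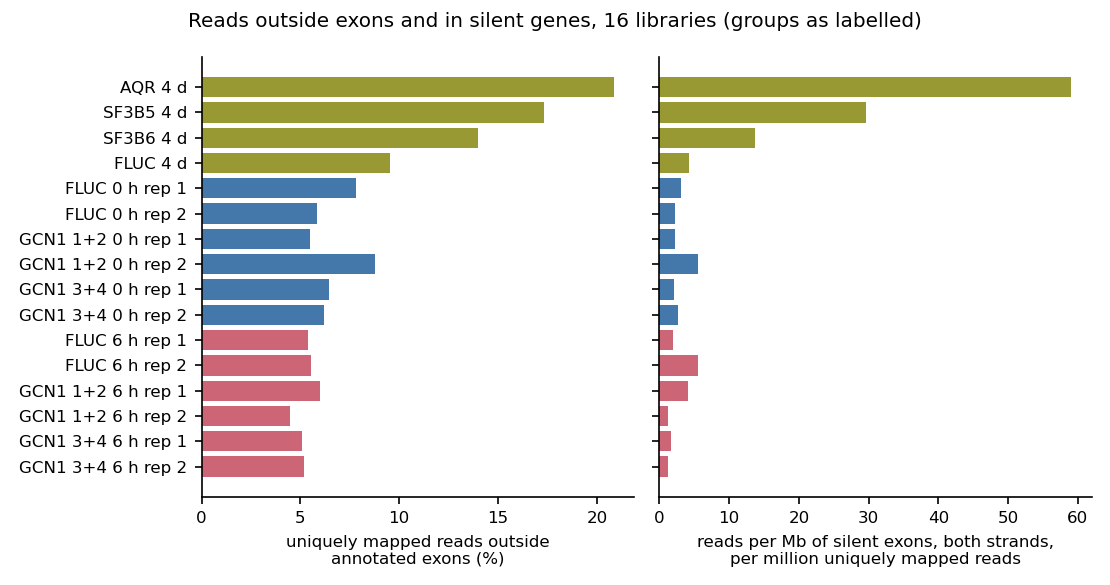
Left, percent of uniquely mapped reads outside annotated exons of their strand in each of the 16 libraries. Right, reads in exons of genes silent in the 7-day libraries, in RPM of uniquely mapped reads per megabase of exon. The 4-day AQR, SF3B5 and SF3B6 libraries lie at 20.8%, 17.3% and 14.0% and at 59.1, 29.7 and 13.8 RPM per megabase, above FLUC at 9.52% and 4.21.

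The 4-day knockouts ask what loss of single spliceosome parts does to mRNA levels, and with 1 library per group they have no replicate check and no p-value. AQR (chromosome 15, 34851782 to 34969742) encodes a helicase that binds introns in the spliceosome, and SF3B5 (chromosome 6, 144094884 to 144095573) and SF3B6 (chromosome 2, 24067586 to 24076373) encode small subunits of SF3b, the part of the U2 snRNP that holds the branch site. Each target was lower in its own library. AQR was at 44 CPM against 74.1 in FLUC (log2 ratio −0.75, 95% counting interval −0.92 to −0.59), SF3B5 at 37.3 against 77.4 (−1.05, −1.22 to −0.89) and SF3B6 at 65.8 against 85.8 (−0.38, −0.50 to −0.26). SF3B6 was higher in the SF3B5 knockout (0.78, 0.68 to 0.89), and GCN1 was lower in the AQR (−0.49) and SF3B5 (−0.76) knockouts.

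In the AQR knockout the U6 small nuclear RNA gene RNU6-1 had 121 counts against 0 in FLUC, at least 67.1-fold higher against a floor of 3 counts (the counting interval starts at 5.75 on the log2 scale, which is lower), but 107 reads lay on the other strand and U6 has near-identical copies, so this value is uncertain. RNU4-1, for U4 and with copies of its own, was higher by 3.23 (2.66 to 3.98), the deacetylase HDAC9 by 3.15 (2.52 to 4.02) and the proteasome subunit PSMA2 by 3.04 (2.47 to 3.80). TTN, at 3.40, is uncertain because an antisense gene overlaps it. SLC13A4 was the lowest, with 3 counts against 142 (−4.52, −7.12 to −3.25), then LINC01003 (−4.11), PARP9 (−3.95), PRKCQ (−3.78) and RASL11A (−3.55). The CLK kinases that phosphorylate SR proteins were higher, CLK2 by 0.94 and CLK1 by 0.81. Of 10502 genes, 137 were over 2-fold higher and 467 over 2-fold lower.

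In the SF3B5 knockout SGK1 was higher by 2.99, ATF3 by 2.28, CCN2 by 2.01, PPP1R15A by 1.84, GADD45A by 1.66 and DDIT3 by 1.62. The highest ratios were in genes nearly silent in FLUC, PHKG1 (156 counts against 1, 6.59, 5.24 to 13.1), FNDC7 (109 against 2, 5.54, 4.34 to 9.29), NPR3 (5.28), the muscle gene CMYA5 (715 counts against 29, 5.02, 4.55 to 5.67) and ANKRD1 (4.27). PHKG1 had 27 reads on the other strand in FLUC and 16 in the knockout, so its value is uncertain. The lowest ratios were in MLXIPL (−3.28), BMP8B (−3.21), ALDH1A3 (−3.07), RELL2 (−2.96) and TLCD2 (−2.77). Of single spliceosome genes, BUD31 was higher by 1.20, CWC15 by 1.19, SF3B4 by 1.09 and SNRPB2 by 1.02, although only 7 of 15 U2 and SF3b genes lay above FLUC and their median was −0.01. The kinase genes CLK3 (1.47), CLK1 (1.24) and TTK (1.39) were higher. The sterol enzymes FDPS and LSS were lower (−0.98 and −0.94), as was DDIT4 (−1.20). Of 10588 genes, 444 were over 2-fold higher and 644 lower. Without TMM scaling the median of all genes moved from −0.05 to −0.28 and these counts to 213 and 1191, so the SF3B5 values are relative to that scaling.

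In the SF3B6 knockout the highest ratios were in RRH (2.48), EGLN2 (2.20), SNORD3A (2.07, uncertain for its copies), HOXA6 (1.99, 613 counts against 168) and HOXA11-AS (1.93). The lowest were NUDT13 (−3.01), SOX5 (−2.52), ATP2A1-AS1 (−2.47), RYR2 (−2.16) and ADGRB3 (−2.11). HOXA11-AS carries more reads on the other strand in both libraries and NUDT13 in the knockout library (140 against 13), and both are uncertain. CLK3 was higher by 1.21, the spliceosome gene CTNNBL1 by 0.85 and the early genes GADD45B and SGK1 by 1.62 and 1.18, while of the p53 targets TIGAR was higher (1.30) and FDXR lower (−1.48). Of 10622 genes, 85 were over 2-fold higher and 161 lower. With at least 500 counts, 13 were higher and 5 lower in SF3B6, 206 and 182 in SF3B5 and 11 and 60 in AQR. With at least 20 counts these were 813 and 820, 1192 and 1502, and 1207 and 1418, and with all libraries thinned to the same total 43 and 71, 354 and 441, and 124 and 246. The balance of higher and lower genes therefore depends on the minimum in all 3 knockouts, and in AQR on depth too. Between 7-day replicates, 1 to 83 genes differed over 2-fold by the same measure.

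The snoRNA host genes, whose introns carry small nucleolar RNAs and whose spliced transcripts are often degraded by NMD, were higher in all 3 knockouts. Their median log2 ratio was 0.69 in AQR, 0.79 in SF3B5 and 0.47 in SF3B6, above all of 10000 random lists matched on expression in each (percentile 100), with 13 of 16 members higher in each knockout. The random lists ignore any correlation between members, and the 3 knockouts share 1 FLUC library, so a deviation of that library could raise a list in all 3 and these are not 3 independent results. SNHG1 was higher by 0.88, 1.75 and 0.86 in the same order. SNHG5 was higher by 1.37 in AQR and 1.90 in SF3B5, SNHG12 by 1.14 in AQR, ZFAS1 by 1.52 in SF3B5, and SNHG17 and TAF1D by 1.03 and 0.80 in SF3B6. Cytosolic ribosomal protein genes were higher too, with medians of 0.23, 0.47 and 0.29 (percentile 100 each) and 69, 75 and 78 of 78 above FLUC, RPL22 by 0.86 in AQR and 0.73 in SF3B6, RPL26 by 0.83 in AQR, and RPL39 by 1.09 in SF3B5 and 0.68 in SF3B6. The intron-binding and PRP19 complexes stood at 0.26, 0.50 and 0.26 (percentiles 99.6, 99.8 and 99.8), with ZNF830 at 0.54 in AQR.

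In the lists of this paragraph the SF3B5 median lay furthest from 0 of the 3 knockouts with TMM scaling. With library totals the AQR median lay further for histones (0.33) and mitotic genes (0.17). Differences between knockouts were not tested. Immediate early genes had a median of 0.80 in SF3B5 (percentile 100, 9 of 20 over 2-fold higher), −0.10 in AQR (46.9) and 0.18 in SF3B6 (98.5). Mitochondrially encoded mRNAs had 0.83 in SF3B5 (100, all 13 higher, MT-CO2 by 1.37 and MT-CYB by 1.11), 0.22 in AQR (99.9) and 0.19 in SF3B6 (93.9). Cholesterol synthesis genes were at −0.44 in SF3B5 (0.07) but −0.05 in AQR (48.7) and 0.04 in SF3B6 (71.2). ATF4 targets were at −0.28 in SF3B5 (0.24), −0.14 in AQR (10.7) and −0.11 in SF3B6 (1.11), although SLC3A2 was higher by 1.16 in SF3B5. Histone genes were at 0.32 in AQR (99.2, H3C10 by 1.31 and H4C3 by 1.14), 0.51 in SF3B5 (99.8) and −0.06 in SF3B6 (53.6). NF-kB genes, 6 measured, were at 0.72 in SF3B5 (99.6), 0.32 in AQR (95.3) and −0.13 in SF3B6 (38.7). Mitotic genes were at 0.16 in AQR (99.4, AURKB by 0.87), 0.36 in SF3B5 (96.7) and 0.00 in SF3B6 (30.8).

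Of the other lists, p53 targets had a median of 0.28 in SF3B5 (percentile 97.0), −0.08 in AQR (55.7) and −0.02 in SF3B6 (56.7), with XPC at −0.93 in AQR. SR proteins and CLK kinases were at 0.35 in SF3B5 (96.6), 0.07 in AQR (89.96) and 0.15 in SF3B6 (94.5). Single-exon genes, 141 measured, were at 0.19 in SF3B5 (100), 0.00 in AQR (96.8) and 0.03 in SF3B6 (94.9), and these medians were −0.03, 0.01 and −0.03 with library totals. GCN and collision factors were at 0.03 in AQR (82.9, RNF25 by 1.57), 0.18 in SF3B5 (82.3, −0.05 with library totals) and 0.12 in SF3B6 (94.2). Heat shock genes were at 0.12 (93.7), 0.05 (41.9, −0.18 with library totals) and 0.10 (75.1) in AQR, SF3B5 and SF3B6. U2 and SF3b genes were at 0.13 (96.5, SF3B4 by 0.70), −0.01 (26.7) and 0.16 (94.6), unfolded protein response genes at −0.15 (15.2), −0.10 (17.4) and −0.05 (25.7), and NMD factors at 0.06 (82.8), −0.11 (20.95) and 0.02 (51.9, −0.05 with library totals). With library totals the SF3B6 medians of cholesterol synthesis and mitotic genes were −0.02 and −0.06, also of the other sign. In SF3B5 library totals lowered every list. The medians became 0.05 for p53 targets, 0.12 for SR proteins and CLK kinases, 0.13 for mitotic genes, 0.24 for ribosomal proteins, 0.27 for the PRP19 complexes, 0.28 for histones, 0.49 for NF-kB genes, 0.56 for snoRNA hosts, 0.57 for immediate early genes and 0.60 for mitochondrial mRNAs. Those below 0 became −0.24 for U2 and SF3b genes, −0.33 for the unfolded protein response, −0.34 for NMD factors, −0.51 for ATF4 targets and −0.67 for cholesterol synthesis. In SF3B6 the medians became 0.04 for heat shock genes, 0.06 for collision factors, 0.09 for SR proteins and CLK kinases, 0.10 for U2 and SF3b genes, 0.11 for immediate early genes and 0.13 for mitochondrial mRNAs, and −0.08 for p53 targets, −0.11 for the unfolded protein response, −0.13 for histones and −0.17 for ATF4 targets.

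**Figure D4:**
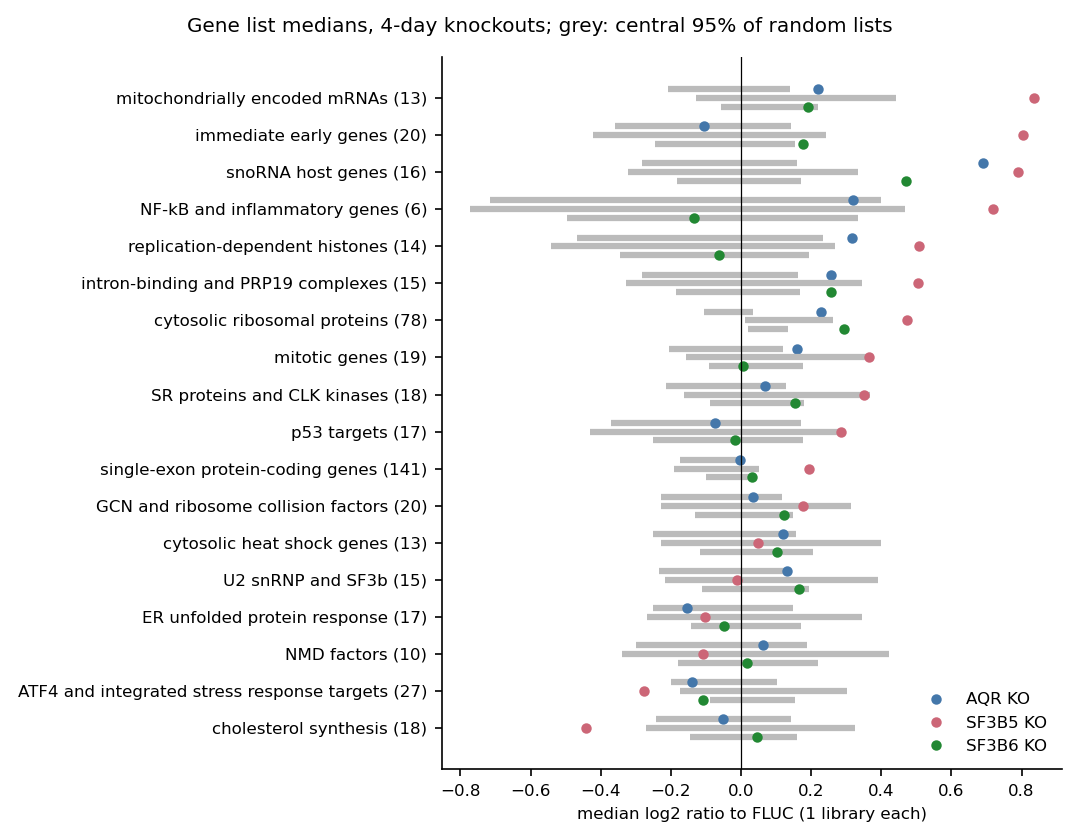
Median log2 ratio to FLUC of each gene list in the 4-day AQR, SF3B5 and SF3B6 knockouts (number of genes measured in parentheses), with grey bars for the central 95% of 10000 random lists matched on expression. The snoRNA host genes lie at 0.69, 0.79 and 0.47, and with library totals in place of TMM some medians near 0 change sign, such as that of heat shock genes in SF3B5 (0.05 to −0.18).

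The 3 knockouts were compared with each other through their shared FLUC library. Over 2-fold, 29 of 10763 genes were higher in all 3 and 15 lower. Across genes, which are not independent replicates, the log2 ratios of AQR and SF3B5 correlated at r = 0.412, of AQR and SF3B6 at 0.404 and of SF3B5 and SF3B6 at 0.478, below the 0.486, 0.489 and 0.498 that unchanged libraries gave in 100 simulations with the same control. The covariances were 0.148, 0.0909 and 0.127 against 0.0302, 0.0304 and 0.0305 simulated. In the same order 74, 36 and 57 genes were over 2-fold higher in both, against 7.26, 1.61 and 4.26 for independent lists and 1.06, 1.14 and 1.20 simulated, and 109, 44 and 43 were lower in both, against 30.3, 7.90 and 10.4 independent and 1.06, 1.16 and 1.03 simulated. The control is a single library and cannot be split, so part of the excess may come from it. The simulations also took their spread from the 7-day replicates. If the 4-day libraries vary more, the simulated values are too low, which could not be checked without 4-day replicates.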

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

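Tests of the genes called at 0 h within the 6 h libraries, of genomic DNA and of unspliced transcripts were chosen after the results were seen. The tests of the GCN1 level under each set of names and of other splits of the 12 libraries were chosen before. A margin beyond the range of replicates was not part of what was predicted for right labels.

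The response to harringtonine differed between labelled GCN1 knockout and labelled FLUC for 1603 genes, and EGR1 differed most among the genes named, by −4.93 on the log2 scale. These differences between groups followed the 6 h pair labelled guides 3 and 4, in which EGR1 averaged 12.1 CPM against 1921 and 1972 in the other 6 h pairs. If the file names are right this pair is FLUC, and the strong induction of immediate early genes belongs to the GCN1 knockouts. If the labels are right, the knockout pairs differed from each other in this response, and edgeR called 0 genes between the pairs labelled guides 1 and 2 and FLUC (1506 at an unadjusted p under 0.05, 0 by DESeq2).

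The GCN1 level does not settle which names are right. By labels the knockout minus FLUC difference at 6 h was −0.50, the direction the labels need. Both labelled FLUC libraries lay above every labelled knockout library, as written beforehand for right labels. The groups were only 1.48 CPM apart while replicates differed by up to 26.5 CPM, so this met prediction is weak evidence. By file names the difference was 0.71, so that the FLUC pair would hold the least GCN1 transcript. This is the opposite of 0 h and of what right file names were predicted to give. If NMD lowers GCN1 in the knockouts, which was not tested here, the drug could remove the difference seen at 0 h, because NMD needs translation and harringtonine stops it. That alone gives no ground for a FLUC level below the knockouts. The FLUC libraries, at 432 and 470 CPM at 0 h, stood at 199 and 226 CPM at 6 h by labels and at 131 and 112 by file names. GCN1 fell by 0.57 with the drug on average. An exchange of labels and an error in the file names cannot be told apart from this level, because no 6 h library of known genotype shows what the drug does to it.

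The genes called at 0 h other than GCN1 were then followed into the 6 h libraries. Of 21, 17 were nearest to FLUC in the 6 h pair whose files are named FLUC, and 13 of 17 without immediate early genes, whereas 1 was nearest to FLUC in the pair labelled FLUC. Right labels with 0 h differences that persist need most of the 21 there. An exchange of the 6 h labels is therefore a candidate explanation, and a hypothesis, since the pairs were known to differ before this test was made and the drug moves many of these genes.

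The drug contrast does not depend on these names. Of 100 splits of the 12 libraries into 6 and 6, out of 462 possible, 1 gave as many genes as the real one. It was the real split itself, with 7657 genes in that fit against 1094 in the highest other. A random regrouping of single libraries therefore did not give such a count. Because replicates may be technical and the splits separate them, a difference between the cultures of the groups is not excluded.

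Reads that the comparisons do not use stood above FLUC in the 4-day knockout libraries. Unmapped reads were 65.2% in AQR, 57.7% in SF3B5 and 57.4% in SF3B6 against 45.8% in FLUC. Reads in the exons of silent genes, on both strands, were 690, 475 and 236 per Mb against 72.1 in FLUC. Scaled to uniquely mapped reads they were 14.0-fold, 7.04-fold and 3.27-fold the FLUC level.

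The share of reads outside exons followed the same order, and genomic DNA carried into the libraries is a candidate explanation: it puts equal numbers of reads on both strands of silent genes, and 1157 sense and 1044 antisense reads lay there in AQR, 14.0-fold the FLUC level after scaling to uniquely mapped reads. Scaled to the genome this excess would make up 15.97, 7.41 and 2.78 points of the uniquely mapped reads, beside 11.3, 7.78 and 4.45 points of excess outside exons. That scaling assumes an even spread. In AQR, SF3B5 and SF3B6 the reads lay in only 204, 269 and 126 of the 1672 silent genes, against 89 in FLUC. They numbered 10.8, 5.63 and 5.98 per gene with reads, against 2.58 in FLUC. Such piles go against genomic DNA spread evenly, and the scaled values are uncertain. Unspliced transcripts after loss of a splicing factor, the biological explanation, cannot be told apart. It was measured by reads on the host strand in nested silent genes, less those on the other strand and scaled to gene counts. These were 1.24, 1.44 and 1.45-fold those of FLUC in AQR, SF3B5 and SF3B6. The ratio was lowest in AQR, where the excess outside exons was largest, and SF3B5 and SF3B6 were alike within counting error. All lay within the widest ratio between 7-day replicates, 1.77 for guides 1 and 2 at 0 h, and within the next, 1.55 for FLUC at 0 h. The nested genes were chosen for no sense read at 7 days, so nothing was subtracted there. At 4 days 971 reads were subtracted in AQR and 102 in FLUC. The 7-day ratios are therefore an unlike yardstick, and this measure cannot decide. The 12 libraries of 7 days lay between 1.21 and 5.55 RPM of uniquely mapped reads per Mb in silent genes, against 4.21 in FLUC at 4 days.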

How the results depend on the processing

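Leaving out the 6 h pair labelled guides 3 and 4 and crossing the replicate numbers of guides 1 and 2 at 0 h were chosen after seeing the data, and all other alternatives before. Of 135 alternative values for the comparisons, 80 stayed the same, 53 moved, 1 was weaker and 1 reversed. Of 1585 for single genes at 7 days, 1436 stayed the same, 100 lost their call, 22 gained one and 27 reversed. Of 372 at 4 days, 324 stayed within their counting interval and 48 moved. Apart from the file names and the scaling splits below, the cause was not tested.

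The harringtonine count of 9168 stayed within 1.5 times in every alternative, from 8321 with DESeq2 to 9589 with 1 library left out, and was 8425 without the added pair and 9105 with crossed numbers. Every gene given with a value for the drug kept its call in the alternatives fixed beforehand. Single genes were not followed in the 2 added ones, where 7746 and 9052 of the 9168 genes kept their call. Without the pair 19 of the 9168 had the opposite sign.

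For knockout against FLUC at 0 h the 22 calls became 53 with DESeq2, 61 without the filter and 5 with only the compared groups, and 1 to 1307 with 1 library left out. For guides 1 and 2 the 9 became 37, 53 and 3, and 16 with library totals, and 1 to 2523. For guides 3 and 4 the 4 became 19, 28 and 21, and 1 with any library left out. Library totals gave 75.9% rises at 0 h against 63.6%, of 29 calls, and 75.0% against 55.6% for guides 1 and 2.

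At 6 h the labelled count of 1641 became 3862 with only the compared groups and 3951 by file names, and 95 to 1296 with 1 library left out. Library totals gave 76.0% rises against 41.4%. The interaction count of 1603 became 801 by file names and 102 to 4778 with 1 library left out, and library totals gave 60.5% rises against 47.0%. By file names, library totals moved the median of all genes to −0.18 at 6 h and −0.22 for the interaction. A fit of only the compared groups is the same fit for the drug and the interaction.

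File names reversed the GCN1 level at 6 h to 0.709 and these log2 fold changes: GCN1 0.71, KIT −1.89, BMF −1.45, GUCY1A1 −2.01, EPHA3 −1.12, FOSB 3.66, MIR222HG 2.93, PPP1R15A 1.80, TLN1 1.36, EGR1 7.33, ATF3 4.60, FOS 5.79, DUSP1 3.71, DDIT3 1.43, SESN2 0.82, XPOT −0.60, H1-2 1.45, H3C2 1.41, RPL26 0.88, MT-CO1 −0.25, SMG5 0.68, SF3B2 0.47 and CDKN1A 1.55. The interaction became 6.10 for EGR1, 4.03 for ATF3, 4.39 for FOS and −1.52 for KIT. The alternative's own construction, other libraries in each group, is the cause.

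By file names at 6 h, immediate early genes rose, 28 of 37 with 2 falls (camera adjusted p = 2.9e-92, and 0.000336 with an estimated correlation), and histones rose, 17 of 21 (5.9e-19 and 0.00534). Lists called under the labels went from 7 to 1 with an estimated correlation, those at 0 h from 9 to 4 and those for the drug from 12 to 5.

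The replicate block gave 17 calls at 0 h, 9 and 3 for the guide pairs, 9020 for the drug, 1406 at 6 h and 1415 for the interaction. With the samples paired, the fall in reads outside exons at 6 h of −1.50 points had an exact sign-flip p of 0.0938 by labels and 0.0313 by file names. Of the lists and the genes named for these comparisons, the block changed no other call than those given in the report.

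At 4 days the counts over 2-fold depend on depth. For AQR the 604 became 2625 with at least 20 counts, 71 with at least 500 and 370 when thinned. For SF3B5 the 1088 became 2694, 388 and 795, and with library totals 1404, of which 15.2% were higher against 40.8%. For SF3B6 the 246 became 1633, 18 and 114. With at least 500 counts the correlations were 0.470 for AQR and SF3B5, 0.509 for AQR and SF3B6 and 0.513 for SF3B5 and SF3B6.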

Other observations

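HBB, the gene for adult beta-globin, was abundant in all 4 libraries of the 4-day experiment and nearly absent from the 12 libraries of the 7-day experiment. It had 20595 counts in AQR, 47804 in SF3B5, 43128 in SF3B6 and 35239 in FLUC, and 33 counts over the 12 7-day libraries together. HBD had 2632, 6370, 5604 and 5378 counts in the same order and 95 over the 7-day libraries. HBB and HBD are related genes, and the split of reads between them was not checked. HBA1, HBA2, HBG1 and HBG2 had 0 counts in each of the 4 libraries, and ALAS2 had at most 2. Multimapping reads are not in these counts, so 0 does not prove absence for genes with close copies. The origin of these reads was not tested.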
